A study of Arabidopsis thaliana with 13 samples.

How the data were processed

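Total RNA of Arabidopsis thaliana leaves was labelled with Cy3 and hybridised to Agilent 1-colour arrays, 1 array per biological replicate. The 13 arrays made 4 groups. Wild-type Col-0 gave 3 control and 3 stress arrays, and a homozygous T-DNA insertion line (SALK_021115C, insertion in At5g45000) gave 3 control and 4 stress arrays. Per the labels, stressed plants had carried turnip mosaic virus for 13 days, drought for 5 days and heat for 3 days when their leaves were taken 34 days after germination. Control plants were mock-treated with water, and each replicate pooled the leaves of 5 to 8 plants, so that replicates are pools of different plants. The labels speak of 4 replicates per treatment; those without a deposited array were not analysed here.

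Per the file headers, the intensity of each spot was read with Agilent Feature Extraction 9.5.3.1, which subtracted the background, corrected spatial trends within the array and put surrogate values in place of signals not above background. No scaling between arrays had been applied to these intensity values. The deposited value table of the series holds log2 values that were matched to the scanner intensities: they equal log2 of the processed intensity minus the array's 75th percentile and minus the probe's median over the arrays, within 0.01 for 99.77% of values, with column medians from -0.05 to 0.13. Scale, centring and direction of that table were thereby known. The probe coordinates of the files name the build ath1:Jan2004. The reference table given for gene names belongs to another assembly and served only for symbols and for checking which loci it holds. Neighbouring genes were taken in the order of their locus numbers.

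From the scanner files, log2 of the processed intensity minus the 75th percentile of the same array over its 43803 non-control spots was computed. Spots with an outlier mark (4 to 62 per array) were left out and saturated spots were kept. Spots of 1 probe were averaged. Of 43603 probes, 37540 took their locus from the systematic name and 644 from the gene name, while 873 with several loci and 4546 without a locus were not assigned. The probe with the highest mean stood for a gene with several probes (7519 genes). A gene was tested if its probe was well above background on every array of at least 1 group, which left 19791 of 28501 genes. Of the tested genes, 19603 were found in the reference table, and the others kept the name of the file. Where the mean of a gene's probes turned the direction of a result, the text says so beside the named gene. Another 38 results for named genes and lists kept their direction with the mean of probes but lost their call, and these are not marked.

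All 13 arrays entered 1 linear model with 4 group means in limma 3.58.1 (R 4.3.3, data.table package 1.17.8), with moderated variances that follow the mean intensity, two-sided tests and Benjamini-Hochberg adjustment over the genes tested. A gene was called at an adjusted p under 0.05. The contrasts were stress against control in Col-0, stress against control in the T-DNA line, the T-DNA line against Col-0 in control plants and in stressed plants, and the difference between the stress responses of the lines. Errors given with a log2 change are the standard errors of that model. "Rose", "fell", "higher" and "lower" are used of called genes. A gene not well above background on any array of a group was given only as a bound: the mean of the brighter group against, per array of the dimmer group, the higher of the probe's own value and the lowest signal among probes well above background.

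The following choices were made before the data were examined: the model, the alternatives, 20 gene lists and the rule for named genes. Named genes are At5g45000 with 10 neighbours on each side; in each stress comparison, the 10 largest rises and the 10 largest falls among called genes that were well above background and unsaturated on every array of both groups, with groups that did not overlap; in each list, up to 4 called members with the largest change and members called in the opposite direction; in each comparison between the lines, up to 10 genes in each direction under the same conditions. The lists cover heat shock (40 genes), endoplasmic reticulum chaperones (17), abscisic acid and dehydration (38), salicylic acid defence (30), nucleotide-binding leucine-rich repeat (NLR) immune receptors (29), RNA silencing (15), potyvirus host factors (10), jasmonate and ethylene defence (27), photosynthesis (32), cytosolic ribosomal proteins (17), expansins and xyloglucan endotransglucosylases (20), antioxidant enzymes and glutathione transferases (19), glucosinolates (18), phenylpropanoids and anthocyanins (19), sugar starvation and senescence (23), the circadian clock (11), guard cells (7), phloem (4), dividing cells (6) and floral organs (4). Each list was tested with limma's camera at its preset correlation of 0.01 and again with the correlation estimated from the data, adjusted over the 20 lists of a comparison.

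Slide (4 slides) and scan day (2 days) were taken from the file headers. Slide 1 held stressed plants of both lines, as did slide 3. Slide 2 held control plants of both lines, and slide 4 held control plants of both lines and 1 stress array of the T-DNA line. Alternatives changed 1 choice at a time: background correction by normexp (offset 50), quantile normalization, centring on the array median, the deposited value table, no filter on dim probes, a stricter filter, the mean of all probes of a gene, every probe on its own, genes with saturated spots left out, slide as a fixed or a random block, the replicate number as a block, only the groups of a comparison, other variance models, and each array left out in turn. Scan day as a block and the fit without both arrays of extreme detection were added after seeing the data.

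The model was tested on simulated arrays with the real means and variances of the 19791 genes and 200 changed genes. For 2-fold changes it recovered 76.1% in the stress comparison of Col-0, 85.1% in that of the T-DNA line, 88.1% between the lines in control plants, 82.1% between the lines in stressed plants and 61.2% for the difference of responses. For 1.5-fold changes the last share was 26.9%. False calls made up 2.5% (lines in control plants) to 10% (difference of responses) of all calls. Each 2-fold share rests on a single draw with 67 changed genes, so differences between comparisons may be noise of the draw. The simulated noise was independent between genes. With 200 changed genes the setting also differs from the real stress comparisons, where 62.7% of genes were called. The number of arrays limits the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.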

Results

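Transcript levels were measured in leaves of Arabidopsis thaliana with 13 arrays of 45220 spots each. Control plants of the wild type Col-0 gave 3 arrays and stressed plants 3, while control plants of a T-DNA insertion line gave 3 and stressed plants 4. The stressed plants met turnip mosaic virus, drought and heat together. The array's 75th percentile of intensity ranged from 1280.8 to 2278.3, and 64.5% to 74.5% of spots were well above background on every array but 1. That array, stressed T-DNA line replicate 4, had 82.1%. Arrays of a group correlated at 0.987 to 0.994 across genes, and arrays of opposite treatment at 0.911 to 0.936. The first principal component, which held 78.2% of the variance, separated stressed from control arrays, and the next held 3.7%.

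The level of the gene that carries the insertion was read first. AT5G45000, described in the files as a transmembrane receptor, was measured by 1 probe on chromosome 5 from 18183915 to 18184064 (build ath1:Jan2004). In control plants its mean log2 level was -1.15 in Col-0 (n = 3) and -3.25 in the T-DNA line (n = 3), a difference of -2.10 ± 0.27 (limma adjusted p = 5.79e-04), or 4.28-fold lower. Every T-DNA array lay below every Col-0 array there. Combined stress lowered the transcript in both lines, by a log2 change of -3.66 ± 0.27 in Col-0 (adjusted p = 2.43e-08) and -2.34 ± 0.25 in the T-DNA line (adjusted p = 1.17e-06). In stressed plants the means were -4.81 in Col-0 and -5.59 in the T-DNA line, and the difference of -0.78 ± 0.25 did not pass the test (adjusted p = 0.136). It passed without stressed T-DNA line replicate 2, at -1.05. The stress responses of the gene differed by 1.32 ± 0.37 between the lines (adjusted p = 0.132), and with slide as a fixed block this difference of 1.42 was called (adjusted p = 0.0476). With normexp background correction the stress changes of AT5G45000 were -2.76 in Col-0 and -0.99 in the T-DNA line (adjusted p = 0.0457). The control plants then differed by -1.69 (adjusted p = 0.0496), and the difference in stressed plants turned to 0.08 (adjusted p = 0.937). Within slides, the control plants differed by -2.32 and -2.04 and the stressed plants by -0.21 and -1.03. The probe was well above background on all 13 arrays, so signal of this probe remained in the insertion line. Whether all of that signal came from AT5G45000 was not tested. The files do not place the insertion relative to the probe. Of the 20 neighbouring genes, 10 were tested. AT5G45020 (-0.43 ± 0.10, adjusted p = 0.0402) and AT5G45030 (-0.46 ± 0.11, adjusted p = 0.0385) were lower in control plants of the T-DNA line, and no other neighbour was called between the lines in either treatment.

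**Figure D1:**
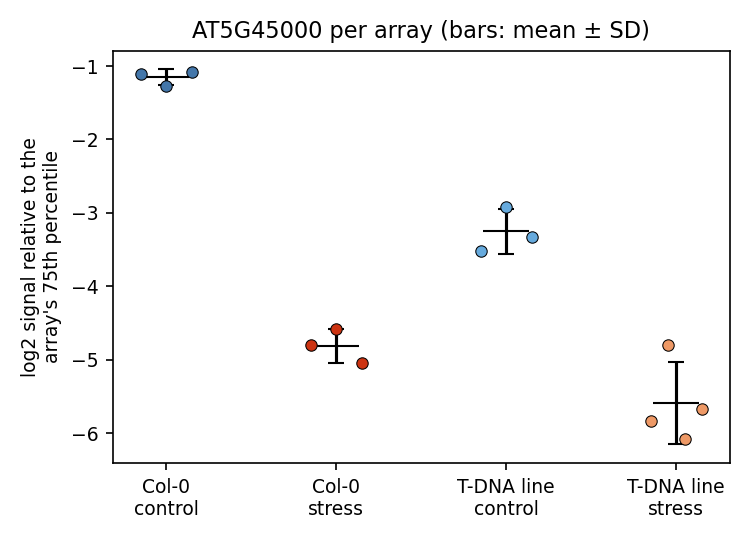
Level of AT5G45000 on each of the 13 arrays, as log2 signal relative to the array's 75th percentile, by group (points: arrays; bars: mean and SD). Control Col-0 arrays lie near the mean of -1.15, control arrays of the T-DNA line near -3.25, and stressed arrays of both lines lowest.

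The first comparison asked which transcripts combined virus, drought and heat changed in wild-type leaves. Heat shock protein genes made up a large part of the strongest rises. The mitochondrial small heat shock protein HSP23.5 rose by 6.96 ± 0.22 on the log2 scale (124-fold, adjusted p = 5.11e-12, n = 3 and 3), the cytosolic chaperone HSP70-4 by 6.93 ± 0.18, and the co-chaperone HOP3 by 7.27 ± 0.12. Of the photosynthesis list 26 of 32 tested genes fell, the light-harvesting LHCB2.3 by a log2 change of -3.78 ± 0.10. Of the salicylic acid defence list 19 of 26 fell and 1 rose, with WRKY38 at -3.70 ± 0.23. Neither list passed camera with an estimated correlation (adjusted p = 0.354 and 0.168). In all, 12412 of 19791 genes were called, 6061 higher and 6351 lower, and 4134 of them changed at least 2-fold.

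The largest rise among genes measured on every array of both groups was that of AT4G23680, a gene related to major latex proteins (8.78 ± 0.23, 438-fold). The other probes of that gene gave 7.55 and 2.65. Next to the heat shock protein genes stood DR4, annotated as drought-repressed (6.46), and the iron-deficiency regulator BHLH100 (6.29). The galactinol synthase GOLS1 (6.27), itself on the heat shock list, and AT4G23493 of unknown function (6.12) followed. HSP17.8 (6.01) and HSP18.2 (5.92) completed the 10 largest rises. The largest falls under the same condition were those of AT3G16530, a legume lectin (-6.83 ± 0.20, 114-fold lower), the putative thionin AT1G66100 (-5.99), the putative chitinase AT1G02360 (-5.27) and the gibberellin-responsive AT1G22690 (-4.94). They were followed by the glutathione transferases GSTF2 (-4.82) and GSTF7 (-4.36), the pseudogene AT1G69140 (-4.63), the copper-binding AT1G31690 (-4.59), the beta-1,3-glucanase BG3 (-4.51) and the pectin methylesterase inhibitor AT5G62360 (-4.32). The largest adjusted p among these 20 genes was 2.65e-06.

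Of 38 tested genes of the heat shock list, 34 rose and 1 fell in Col-0, with a median log2 change of 4.50 (camera adjusted p = 6.5e-20; adjusted p = 0.168 with an estimated correlation). Adjusted over the list alone, 34 rose and 1 fell too. Small heat shock proteins that were not well above background in any control array rose by bounds alone: HSP17.6C at least 2880-fold, HSP23.6 at least 870-fold, HSP22.0 at least 483-fold and HSP17.4 at least 189-fold. HSP70-3 was the member that fell (-0.67 ± 0.18). Among chaperones of the endoplasmic reticulum, 8 of 17 rose and 3 fell, 9 and 3 adjusted over the list alone (camera adjusted p = 0.18, median 0.31). ERDJ3A rose by 2.66 ± 0.19, SDF2 by 0.78 and ERDJ3B by 0.69, while BIP3 (-2.75 ± 0.75), CRT3 (-0.64) and PDIL1-1 (-0.57) fell.

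Genes of abscisic acid and dehydration parted in Col-0: 20 of 38 rose and 13 fell, the same counts as adjusted over the list alone (median 0.48, camera adjusted p = 0.18). The lipid transfer proteins LTP4 (7.41 ± 0.90) and LTP3 (5.74 ± 0.53) and the ABI5-binding protein AFP1 (4.33 ± 0.22) rose. Members that fell included COR15A (-4.15 ± 0.26), COR15B (-3.91), RD29A (-3.74), XERO2 (-3.31), COR413-PM1 (-2.63), KIN1 (-1.29), ERD7 (-1.03), COR6.6 (-0.88), ERD10 (-0.63), COR47 (-0.60) and LEA14 (-0.52). NCED3, which makes a precursor of abscisic acid, fell by -1.22 ± 0.23, and CYP707A1, which breaks the hormone down, by -0.96 ± 0.17. Of the sugar and senescence list, 6 of 21 rose and 8 fell, the same adjusted over the list alone. Its median was 0.07 and its mean 0.18 where camera leaned down (adjusted p = 0.532). The sucrose transporter SWEET15 rose at least 125-fold, the senescence regulator NAC092 by 2.29 ± 0.36, GPT2 by 1.43, NAP by 0.93, APL3 by 0.73 and SGR1 by 0.54, and the sucrose synthases SUS1 (-2.31 ± 0.13) and SUS4 (-2.20 ± 0.17) fell.

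Salicylic acid defence genes were mostly lower in stressed Col-0. Of 26 tested, 19 fell and 1 rose, and adjusted over the list alone 19 fell and 2 rose (median -1.04, camera adjusted p = 6.45e-05; adjusted p = 0.168 with an estimated correlation). WRKY38 fell by -3.70, NIMIN1 by -2.80 ± 0.23, the pathogenesis-related PR5 by -2.72 ± 0.31 and the transporter EDS5 by -2.38 ± 0.18, whereas WRKY46 rose by 1.94 ± 0.33. NLR immune receptors went both ways, with 7 of 29 higher and 13 lower, 7 and 13 also adjusted over the list alone (median -0.16, camera adjusted p = 0.514). RPS6 (1.65 ± 0.13) and TAO1 (1.25) rose, as did CHS3 (0.53), RPP1 (0.49), WRR4 (0.49), RPS4 (0.43) and RAC1 (0.39), and RLM3 (-1.31 ± 0.09) and ZAR1 (-1.10) fell. In the jasmonate and ethylene list, 8 of 24 rose and 9 fell, the same adjusted over the list alone (median 0.03, or -0.04 with normexp background correction, and mean -0.19; camera leaned up, adjusted p = 0.964). The defensin PDF1.2A fell at least 19.5-fold and PR4 by -3.99 ± 0.21. VSP1 (2.96 ± 0.46), VSP2 (2.91), PR3 (2.66), JAZ5 (2.12), ERF1 (1.41), LOX3 (0.79), AOC1 (0.72) and MYC2 (0.57) rose.

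RNA silencing genes rose in Col-0 where they were called: 8 of 14 were higher and none of them lower, the same adjusted over the list alone (median 0.42, camera adjusted p = 0.0337; adjusted p = 0.363 with an estimated correlation). AGO3 rose by 2.41 ± 0.38, the antiviral argonaute AGO2 by 0.84 ± 0.15, DCL3 by 0.70 and DCL2 by 0.66. Among potyvirus host factors and restriction genes, 6 of 10 fell and 0 rose, the same adjusted over the list alone (median -0.23, camera adjusted p = 0.0829). These included the genes that restrict long-distance movement of potyviruses, RTM1 (-1.61 ± 0.26), RTM2 (-1.28) and RTM3 (-0.86), and the translation factor EIFISO4G2 (-0.74).

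Photosynthesis genes fell in Col-0: 26 of 32 were lower and 0 higher, the same adjusted over the list alone (median -0.77, camera adjusted p = 1.05e-07; adjusted p = 0.354 with an estimated correlation). LHCB2.3 fell by -3.78, LHCB1.1 by -3.72 ± 0.14, LHCB2.1 by -2.17 and LHCB1.4 by -2.04. Expansins and xyloglucan endotransglucosylases fell in 13 of 19 cases and rose in 2, the same adjusted over the list alone (median -0.96, camera adjusted p = 0.00493; adjusted p = 0.168 with an estimated correlation). XTH33 (-4.41 ± 0.75), XTH16 (-3.58 ± 0.22) and XTH4 (-2.34) fell, EXPB3 rose by 1.73 and XTH23 at least 2.57-fold. Of 17 cytosolic ribosomal proteins 3 fell, or 1 adjusted over the list alone (median -0.02, camera adjusted p = 0.749): RPL10A (-0.41), RPS6A (-0.30) and RPL27AC (-0.28), all of which lay above 0 and uncalled after quantile normalization. Antioxidant genes rose in 5 of 18 cases and fell in 8, or 6 and 8 adjusted over the list alone (median -0.21, positive after quantile normalization; camera adjusted p = 0.505). GSTF7 (-4.36) and GSTF6 (-3.84 ± 0.37) fell, and UPOX (3.15 ± 0.20), ZAT12 (2.15), CSD2 (1.57), ZAT10 (0.95) and AOX1A (0.77) rose.

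Phenylpropanoid genes rose in 8 of 16 cases and fell in 4, the same adjusted over the list alone (median 0.83, camera adjusted p = 0.152). The anthocyanin regulator MYB75 rose by 3.70 ± 0.23, chalcone synthase CHS by 3.13 ± 0.28 and UF3GT by 2.58 ± 0.86, while FLS1 (-0.77), PAL1 (-0.62) and PAL2 (-0.47) fell. TT19 fell by -2.03 ± 0.44 on its brightest probe and stood at 0.95, uncalled, as the mean of its probes. Glucosinolate genes rose in 1 of 18 cases (MYB34, 0.58) and fell in 5, the same adjusted over the list alone (median -0.16, positive after quantile normalization; camera adjusted p = 0.346), CYP83B1 by -0.85, SUR1 by -0.72 and FMOGSOX1 by -0.68. Of 9 clock genes, sampled from 4 hours before dusk, 2 rose and 7 fell, the same adjusted over the list alone (median -0.44, mean 0.01; camera leaned down, adjusted p = 0.18): CCA1 by 3.47 ± 0.20, RVE8 by 2.33, PRR5 by -1.72 and FKF1 by -1.10. Of 7 guard cell genes 6 fell, the same adjusted over the list alone (median -1.12, camera adjusted p = 0.0167; adjusted p = 0.168 with an estimated correlation), TGG2 by -1.39 ± 0.21, KAT1 by -1.35, HT1 by -1.16 and TGG1 by -1.12. Phloem genes fell in 3 of 4 cases, the same adjusted over the list alone (median -0.56, camera adjusted p = 0.18): SEOR1 by -1.53, SUC2 by -0.78 and PP2-A1 by -0.35. Dividing cell genes fell in 2 of 6 cases, the same adjusted over the list alone (median -0.39, camera adjusted p = 0.354), KNOLLE by -0.72 and AUR1 by -0.46, and the 1 floral gene tested was not called (camera adjusted p = 0.692).

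No slide held control and stressed Col-0 plants together. With slide as a fixed block 7924 genes were called, and as a random block 12094. Only slide 4 held both treatments, and its 1 stress array was T-DNA line replicate 4. In the fit with slide as a fixed block, every difference between stress and control, in Col-0 too, therefore rests on that array. It is the array with the highest share of spots above background, so this setting is a weak check.

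**Figure D2:**
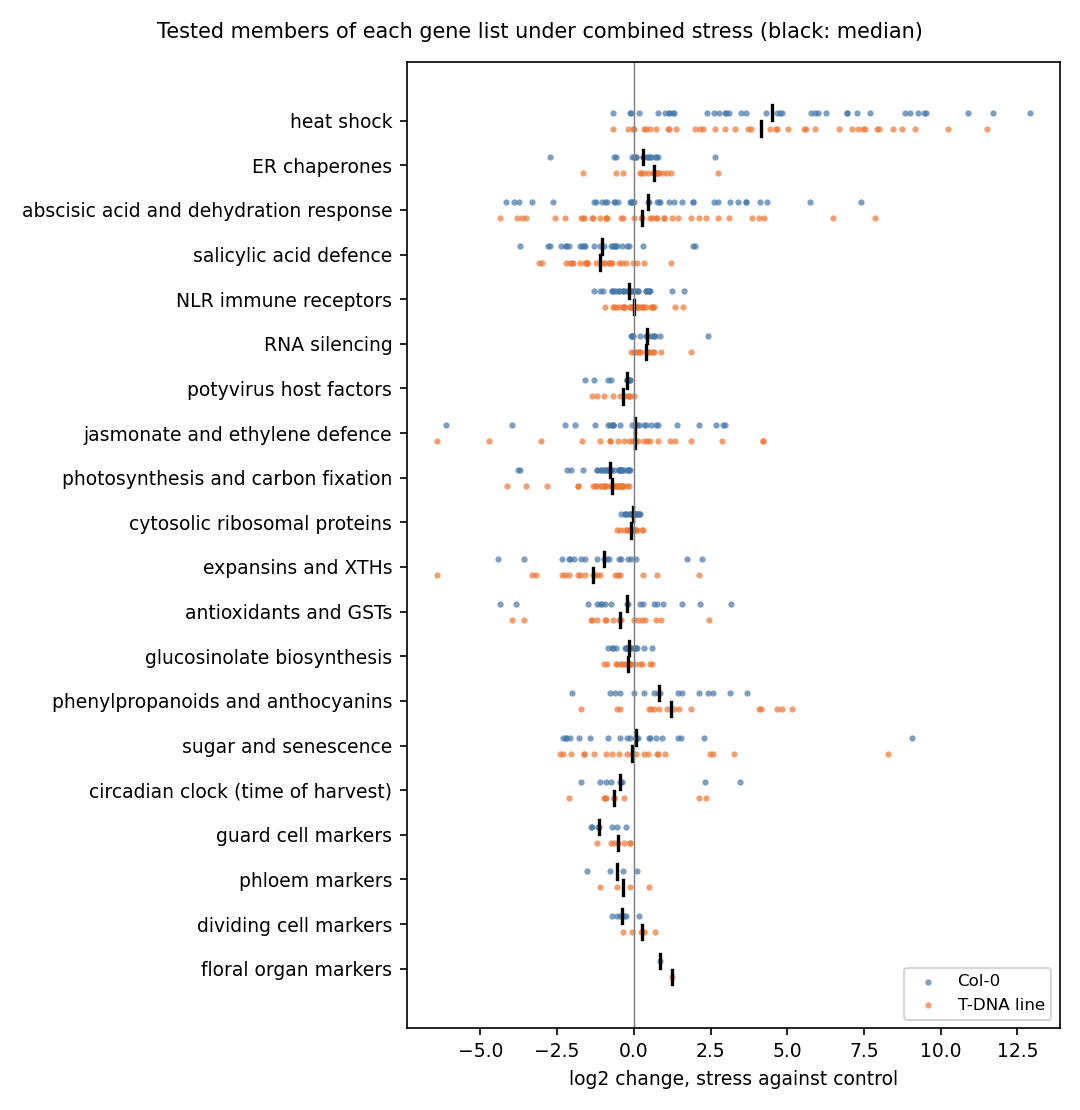
Log2 change under combined stress of each tested member of the 20 gene lists in Col-0 (blue, upper) and the T-DNA line (orange, lower), with the list median as a black bar. The heat shock list has the highest medians of the lists with several tested members (4.50 and 4.13), and the photosynthesis list lies below 0 in both lines.

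The second comparison asked the same of the T-DNA line, where 12404 genes were called, 6262 higher and 6142 lower, 3859 of them at least 2-fold. Of the 10 largest rises among genes well above background on every array of both groups, 5 were genes of heat shock proteins or the co-chaperone HOP3. HOP3 rose by 7.53 ± 0.11 (185-fold, adjusted p = 1.61e-15, n = 4 and 3), HSP70-4 by 7.30, HSP23.5 by 7.10, HSP17.8 by 5.92 and HSP17.6B by 5.62. AT4G23680 (8.42 ± 0.22, 343-fold), LTP3 (6.48), BHLH100 (5.63), GOLS1 (5.55, also on the heat shock list) and the defensin-like AT2G16367 (5.49) were the other largest rises. The largest falls under the same condition were those of the lectins AT3G16530 (-6.78 ± 0.19) and AT3G15356 (-6.23), the thionin AT1G66100 (-4.84), AT2G25735 (-4.77), PR4 (-4.73), the galactolipid synthase MGDC (-4.71), AT1G27020 (-4.65), AT5G62360 (-4.56), AT1G52200 (-4.52) and GSTF2 (-4.37). Within slide 4, which held both treatments of this line, 99.7% of the called genes with a value there had the same direction. These arrays also took part in calling the genes, and 1 of them was a stress array, so this share cannot decide on slide or scan day.

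In the T-DNA line 32 of 38 heat shock genes rose and 1 fell, or 32 and 2 adjusted over the list alone (median 4.13, 4.37 within slide 4; camera adjusted p = 5.32e-17; adjusted p = 0.193 with an estimated correlation). HSP17.4 rose at least 138-fold and HSP17.6II at least 133-fold, HSP17.6C by 11.50 and HSP23.6 by 10.25, each of these last well above background on 1 of 3 control arrays. HSP70-3 fell by -0.67 on its brightest probe and stood at 0.12, uncalled, as the mean of its probes. Endoplasmic reticulum chaperones rose in 12 of 17 cases and fell in 3, the same adjusted over the list alone (median 0.67, camera adjusted p = 0.0103; adjusted p = 0.349 with an estimated correlation), with ERDJ3A at 2.75 and ERDJ3B at 1.06. CRT3 (-0.58), PDIL1-1 (-0.36) and BIP3 (-1.66, but 0.32 and uncalled with slide as a fixed block) fell. Salicylic acid genes fell in 20 of 26 cases and rose in 1, or 22 and 1 adjusted over the list alone (median -1.10, camera adjusted p = 1.27e-05; adjusted p = 0.119 with an estimated correlation): PR5 by -3.11, WRKY38 by -3.00, NIMIN2 by -2.20 and EDS5 by -2.09, against WRKY46 at 1.23. RNA silencing genes rose in 8 of 14 cases, the same adjusted over the list alone (median 0.41, camera adjusted p = 0.0314; adjusted p = 0.33 with an estimated correlation), with AGO3 at 1.85, DCL3 at 0.87, AGO2 at 0.66 and HEN1 at 0.64.

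Photosynthesis genes fell in 31 of 32 cases in the T-DNA line, the same adjusted over the list alone (median -0.71, camera adjusted p = 2.33e-09; adjusted p = 0.312 with an estimated correlation): LHCB2.3 by -4.13, LHCB1.1 by -3.53, LHCB2.1 by -2.84 and LHCB1.4 by -1.81. Expansins and xyloglucan enzymes fell in 16 of 19 cases and rose in 1, the same adjusted over the list alone (median -1.34, camera adjusted p = 1.86e-04; adjusted p = 0.119 with an estimated correlation), XTH33 by -6.41, XTH22 by -3.32, XTH16 by -3.19 and XTH4 by -2.33, with EXPB3 at 2.13. Phenylpropanoid genes rose in 13 of 16 cases and fell in 3, the same adjusted over the list alone (median 1.198, camera adjusted p = 0.00876; adjusted p = 0.349 with an estimated correlation). UF3GT rose at least 14.6-fold, dihydroflavonol reductase DFR at least 13.5-fold, LDOX at least 7.82-fold and MYB75 by 4.13, while PAL2 (-0.55) and PAL1 (-0.44) fell. TT19 fell by -1.72 on its brightest probe but was called higher, at 2.02, as the mean of its probes.

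The remaining lists were not called by camera in the T-DNA line. Abscisic acid and dehydration genes rose in 18 of 38 cases and fell in 16, or 18 and 17 adjusted over the list alone (median 0.26, adjusted p = 0.816). LTP4 rose at least 61.8-fold and the phosphatase HAI2 by 4.25. RD29A (-4.35), XERO2 (-3.82), COR15A (-3.66), COR15B (-3.51) and NCED3 (-2.23) were among the falls, and RD22 (-0.40) stood at 0.00 after quantile normalization. NLR receptors rose in 8 of 29 cases and fell in 8, the same adjusted over the list alone (median -0.003, positive with normexp or quantile scaling, mean 0.07; camera leaned up, adjusted p = 0.85), with RPS6 at 1.62, TAO1 at 1.34, RLM3 at -0.95 and ZAR1 at -0.68. Potyvirus host factors fell in 6 of 10 cases, the same adjusted over the list alone (median -0.36, adjusted p = 0.0507), RTM1 by -1.37, RTM2 by -1.20, RTM3 by -0.96 and EIFISO4G2 by -0.66. Jasmonate and ethylene genes rose in 9 of 24 cases and fell in 7, the same adjusted over the list alone (median 0.03, mean -0.07; camera leaned up, adjusted p = 0.77). PDF1.2A fell at least 25.5-fold, ORA59 by -3.01, PDF1.2B by -1.70, JAZ1 by -1.10 and AOS by -0.77, while VSP1 and VSP2 both rose by 4.22. LOX2 fell by -0.33 but was called higher, at 0.43, after quantile normalization.

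Ribosomal protein genes rose in 1 of 17 cases in the T-DNA line (RPS5B, 0.26) and fell in 3, or in 0 and 2 adjusted over the list alone (median -0.08, positive after quantile normalization; camera adjusted p = 0.561). RPL10A fell by -0.56, and RPL27AC (-0.46) and RPS6A (-0.31) were above 0 and uncalled after quantile normalization. Antioxidant genes rose in 2 of 18 cases and fell in 10, the same adjusted over the list alone (median -0.46, camera adjusted p = 0.0898), GSTF7 by -3.97, GSTF6 by -3.59 and CAT1 by -1.41, with UPOX at 2.46 and AOX1A at 0.35. Glucosinolate genes rose in 2 of 18 cases and fell in 6, the same adjusted over the list alone (median -0.18, positive after quantile normalization; camera adjusted p = 0.233), CYP83B1 by -0.96 and SUR1 by -0.86, with MYB34 at 0.59 and CYP79F2 at 0.53. Sugar and senescence genes rose in 8 of 21 cases and fell in 9, or 8 and 10 adjusted over the list alone (median -0.06, mean 0.30; camera leaned down, adjusted p = 0.58). SWEET15 rose at least 80.5-fold, BAM5 by 3.25 and NAC092 by 2.59. Clock genes rose in 2 of 9 cases and fell in 7, the same adjusted over the list alone (median -0.65, camera adjusted p = 0.0787), CCA1 by 2.36, RVE8 by 2.12, PRR5 by -2.12 and FKF1 by -0.98. Guard cell genes fell in 4 of 7 cases, the same adjusted over the list alone (median -0.53, camera adjusted p = 0.0898), KAT1 by -1.21 and TGG1 by -0.76. Phloem genes fell in 2 of 4 cases (SEOR1, -1.11; SUC2, -0.55) and rose in 1 (APL, 0.51), the same adjusted over the list alone (median -0.34, camera adjusted p = 0.503). Of the dividing cell genes CYCD3;1 rose by 0.69 and KNOLLE fell by -0.34, or 1 and 0 adjusted over the list alone (median 0.27, camera adjusted p = 0.573), and the floral gene SEP3 rose by 1.23, also adjusted over the list alone (camera adjusted p = 0.598).

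The responses of both lines were close to each other. Across the 19791 genes, which are not independent replicates, log2 changes in Col-0 and in the T-DNA line, taken from different arrays, correlated at 0.925 (Pearson) and 0.905 (Spearman), with a slope of 0.882 of the T-DNA line on Col-0. Of 10379 genes called in both, 10349 had the same direction and 30 the opposite. Another 2033 were called in Col-0 and not in the T-DNA line, and 2025 the other way round.

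**Figure D3:**
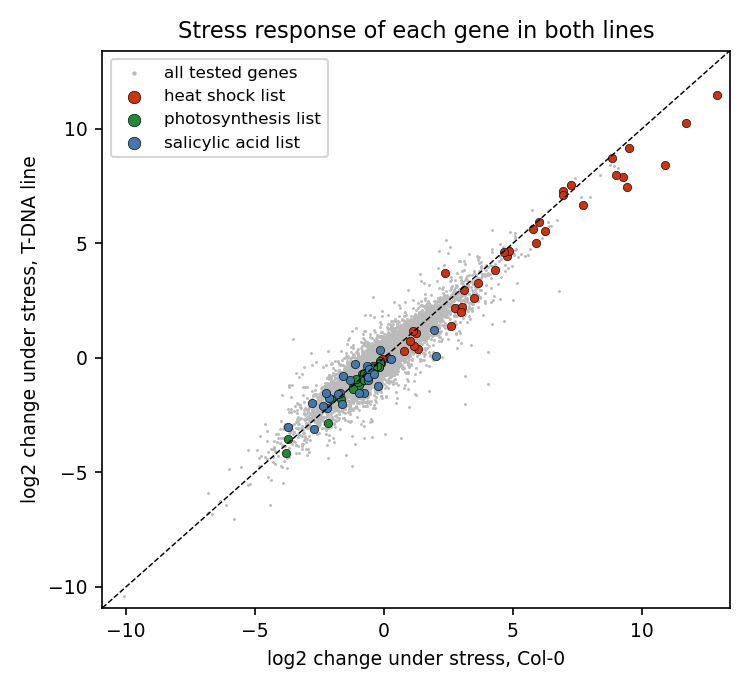
Log2 change of each of the 19791 tested genes under combined stress in Col-0 (horizontal axis) and in the T-DNA line (vertical axis), with 3 gene lists coloured and a dashed line of equal change. The cloud follows the line with a Pearson correlation of 0.925, and the heat shock genes lie at its upper end.

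The third comparison asked how the T-DNA line differed from Col-0 without stress. Among the largest differences of genes well above background on every array of both groups, the phosphate-induced PHI-1 was higher in the T-DNA line by 3.86 ± 0.45 (14.6-fold, adjusted p = 2.45e-04, n = 3 and 3), the touch gene XTH22 by 3.23 ± 0.34 (9.39-fold), the AP2 factor AT1G77640 by 3.17, DREB26 by 2.60, and EXO by 2.42. The transposable element gene AT5G35935 (4.31 ± 0.22, 19.8-fold) and the RNA gene AT2G05995 (3.65 ± 0.20) were the other largest differences upward, with the related genes AT3G19680 (2.65) and AT1G50040 (2.52) and the floral repressor MAF5 (2.22). Lower were the heat shock factor HSFA2 (-2.35 ± 0.32, 5.11-fold), AT5G45000 (-2.10), the monooxygenase AT5G11330 (-1.44 ± 0.09), the receptor-like RLP38 (-1.34), AT1G49450 (-1.30), the transposable element gene AT4G06477 (-1.30), AT4G21930 (-1.25), AT1G04570 (-1.25), AT5G45850 (-1.19) and the ankyrin repeat gene AT4G14390 (-1.17). Few genes were called overall: 366, with 208 higher and 158 lower, 97 of them at least 2-fold.

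Few list members were called between the control plants. Expansins and xyloglucan enzymes were higher in the T-DNA line in 2 of 19 cases (XTH22, 3.23; XTH30, 1.27 ± 0.14) and lower in 0, or 5 and 0 adjusted over the list alone (median 0.25, camera adjusted p = 2.8e-04; adjusted p = 0.127 with an estimated correlation). Clock genes were higher in 2 of 9 cases, PRR5 by 0.86 and LUX by 0.66, also adjusted over the list alone (median 0.23, camera adjusted p = 2.8e-04; adjusted p = 0.127 with an estimated correlation). Photosynthesis genes were higher in 2 of 32 cases, LHCB2.1 by 0.65 and LHCB2.3 by 0.48, also adjusted over the list alone (median 0.07 but -0.02 and -0.01 within slides 2 and 4; camera adjusted p = 0.00309; adjusted p = 0.811 with an estimated correlation). Endoplasmic reticulum chaperones were lower in 1 of 17 cases (BIP2, -0.58), or 2 adjusted over the list alone (median -0.20, camera adjusted p = 3.23e-04; adjusted p = 0.333 with an estimated correlation). No NLR receptor was called among 29, nor adjusted over the list alone (median -0.15, camera adjusted p = 0.00309; adjusted p = 0.333 with an estimated correlation), and no dividing cell gene among 6, nor adjusted over the list alone (median -0.34, camera adjusted p = 0.0185; adjusted p = 0.333 with an estimated correlation).

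The other 14 lists were not called by camera between control plants, at adjusted p of 0.0736 or above. In the heat shock list HSFA2, MBF1C (-1.02) and HSFB2B (-0.72) were lower and HSP23.6 was called higher, although only 1 of 6 control arrays measured it above background, and adjusted over the list alone 1 was higher and 5 lower. Of the abscisic acid list HAI2 (-1.75 ± 0.28), NAC019 (-0.91) and ABI1 (-0.68) were lower and MYB96 (0.61) higher, or 4 higher and 6 lower adjusted over the list alone. WAK1 (-0.50) of the salicylic acid list was lower, with 1 higher and 2 lower adjusted over the list alone, and MYC2 (-0.82) of the jasmonate list was lower, also adjusted over the list alone. In the lists of phenylpropanoids, RNA silencing, potyvirus host factors, ribosomal proteins, antioxidants, glucosinolates, sugar and senescence, guard cells, phloem and floral organs 0 genes were called, and 3 phenylpropanoid genes were lower adjusted over the list alone. Median and camera differed in sign for the potyvirus list (median -0.04, mean -0.03) and the jasmonate list (median -0.10, mean -0.04), both of which camera leaned up. The abscisic acid list had a median of 0.04 and a mean of -0.09. Within slides 2 and 4, each holding control plants of both lines, 100% of the 366 genes kept their direction. Those 366 genes were called from these same arrays, so this share cannot decide on slide or scan day. The count was 156 without Col-0 control replicate 1, 182 without Col-0 control replicate 3 and 166 without T-DNA control replicate 4.

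The fourth comparison asked how the lines differed under combined stress. Of 38 tested heat shock genes, 6 were lower in the stressed T-DNA line and 32 were not called, although all 38 differences lay below 0 (median -0.62). Those called included the coactivator MBF1C (-1.38 ± 0.20, 2.60-fold lower, adjusted p = 0.00351, n = 4 and 3), the heat shock factors HSFB2B (-1.19 ± 0.15) and HSFB2A (-1.13 ± 0.14) and the small heat shock protein HSP15.7 (-1.06 ± 0.18). Adjusted over the list alone, 23 were lower and 0 higher (camera adjusted p = 1.53e-19; adjusted p = 0.212 with an estimated correlation). Of 38 abscisic acid and dehydration genes, 5 were lower and 33 were not called, with 18 lower and 2 higher adjusted over the list alone (median -0.47, camera adjusted p = 9.64e-10; adjusted p = 0.508 with an estimated correlation): AFP1 by -0.96 ± 0.21, HAI1 by -0.90, NAC019 by -0.68 and COR47 by -0.57. Guard cell genes were higher in 2 of 7 cases, or 3 adjusted over the list alone (median 0.46, camera adjusted p = 1.43e-04; adjusted p = 0.0958 with an estimated correlation), TGG2 by 0.98 ± 0.20 and TGG1 by 0.56.

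Over all genes, 288 were called between the stressed lines, 155 higher and 133 lower in the T-DNA line (117 and 127 with normexp, 168 and 209 after quantile normalization), and 48 of them at least 2-fold. Among genes well above background on every array of both groups, AT5G35935 (4.39 ± 0.20, 21.0-fold) and AT2G05995 (3.81 ± 0.19) were the highest, followed by MAF5 (1.80), AT1G31690 (1.64), BZIP34 (1.31), the brassinosteroid oxidase BR6OX1 (1.21), AT1G66100 (1.21), XTH16 (1.17), the myrosinase-binding MBP1 (1.16) and BZIP61 (1.16). The lowest under that condition were the deadenylase CAF1a (-2.19 ± 0.35), DIP2 (-1.70), AT5G11330 (-1.53 ± 0.08), the calmodulin-like CML23 (-1.49), MBF1C, the RNA gene AT2G06002 (-1.25), AT1G26800 (-1.23), the DnaJ gene AT3G14200 (-1.22), HSFB2B and the touch gene TCH2 (-1.16).

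Dividing cell genes had 0 of 6 called between the stressed lines, and 0 adjusted over the list alone (median 0.19, camera adjusted p = 0.0358; adjusted p = 0.508 with an estimated correlation). The other 16 lists were not called by camera there, at adjusted p of 0.078 or above. XTH16 was higher in the expansin list, or 2 genes adjusted over the list alone, and SAG21 (-0.85 ± 0.14) and SGR1 (-0.38) of the senescence list were lower, or 4 genes higher and 3 lower adjusted over the list alone. In the lists of endoplasmic reticulum chaperones, salicylic acid, NLR receptors, RNA silencing, potyvirus host factors, jasmonate, photosynthesis, ribosomal proteins, antioxidants, glucosinolates, phenylpropanoids, clock, phloem and floral organs, 0 genes were called. Adjusted over the list alone, 1 salicylic acid, 1 NLR, 1 photosynthesis, 1 glucosinolate and 3 clock genes were higher and 1 RNA silencing, 3 antioxidant and 1 clock genes lower. Median and camera differed in sign for the salicylic acid list (median -0.03, mean 0.02) and the NLR list (median -0.01, mean 0.02). The potyvirus list had a median of 0.03 and a mean of -0.01. Within slides 1 and 3, 99.3% and 100% of the 288 genes kept their direction, and the heat shock median was -0.23 and -0.97. The arrays of these slides took part in calling the 288 genes, so those shares cannot decide on slide or scan day. The count of 288 fell to 126 without Col-0 stress replicate 1, 187 without Col-0 stress replicate 3, 166 without T-DNA stress replicate 1 and 160 without T-DNA stress replicate 4, the array with the highest share of spots above background. With slide as a random block it was 457, with only the groups compared 174, without a variance trend 178, without the filter on dim probes 185, and without both arrays of extreme detection, an alternative chosen after seeing the data, it was 124.

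**Figure D4:**
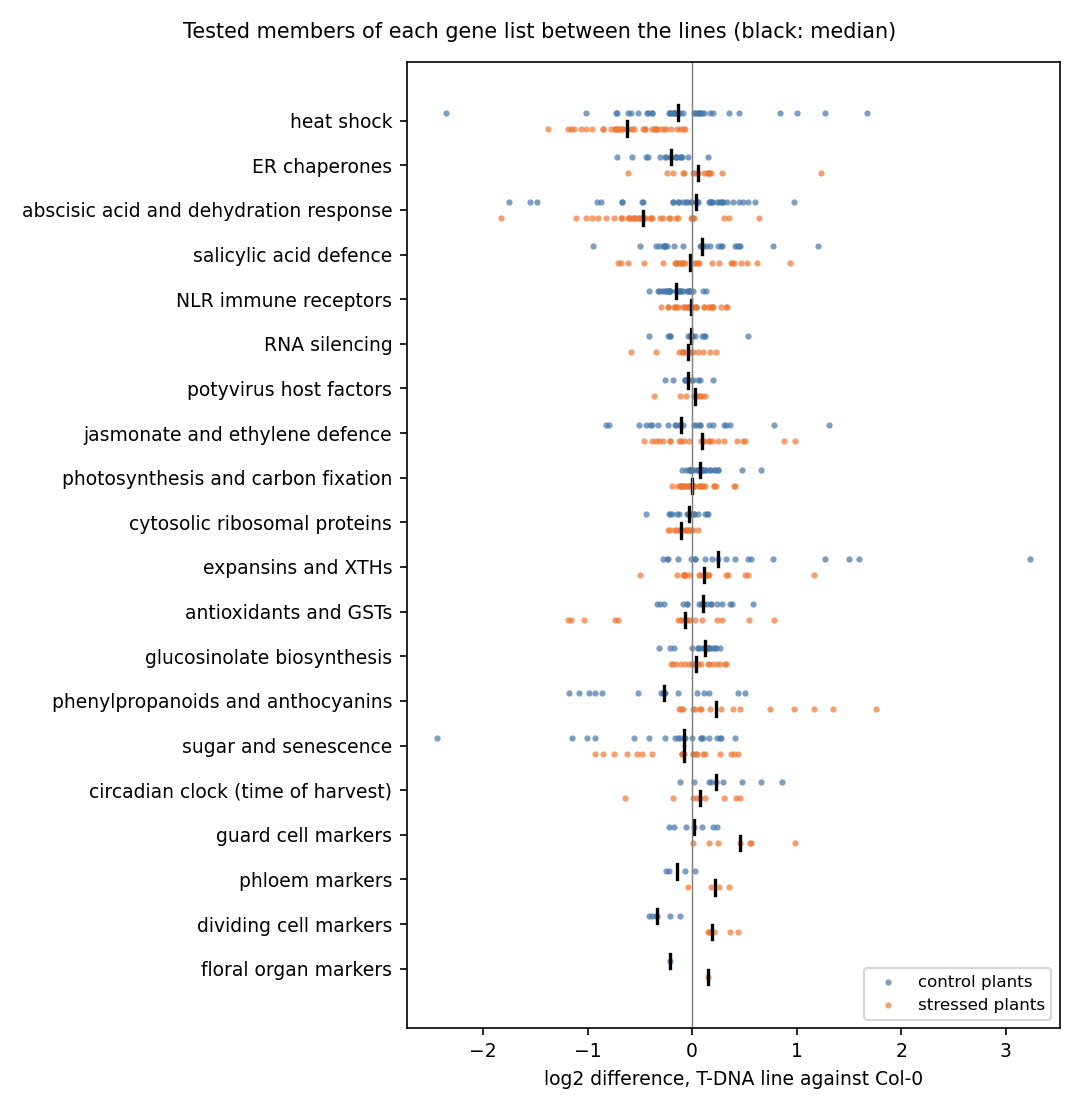
Log2 difference between the T-DNA line and Col-0 of each tested member of the 20 gene lists in control plants (blue, upper) and stressed plants (orange, lower), with the list median as a black bar. All 38 heat shock genes lie below 0 in stressed plants, with a median of -0.62 against -0.13 in control plants.

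The last comparison tested the difference between the stress responses directly. The touch gene TCH2 rose by 1.16 in Col-0 and fell by -0.99 in the T-DNA line, and XTH22, called in the T-DNA line alone, stood at 0.06 and -3.32. Such a difference of responses can come from either treatment. Between the lines, XTH22 differed by 3.23 in control plants and by -0.15, uncalled, in stressed plants. MYB77 (1.94 and -0.31) and ACS6 (1.48 and -0.93) were likewise called in control plants alone. TCH2 (0.99 and -1.16) and CAF1a (0.69 and -2.19) were called in stressed plants alone. Among genes well above background on every array, the largest differences with a lower response in the T-DNA line were those of XTH22, by -3.38 ± 0.47 (adjusted p = 0.00402), the mitochondrial carrier DIC2 by -3.12 ± 0.67, DREB26 by -3.02, CAF1a by -2.88, the ethylene synthesis gene ACS6 by -2.41, AT1G07135 by -2.29, CML23 by -2.27, MYB77 by -2.25 ± 0.18 (adjusted p = 5.08e-05), AT1G50040 by -2.21 and TCH2 by -2.15. Differences in the other direction were those of the expansin EXPA16 (1.82 ± 0.20, adjusted p = 6.53e-04), AT5G55450 (1.79), TED7 (1.77), AT4G14390 (1.74), AT5G45850 (1.63), RLP38 (1.53), the receptor kinase AT5G59670 (1.36), XTH25 (1.36), AT3G27640 (1.34) and the cyclin CYCA3;1 (1.27). Of 149 genes called, 46 had a higher and 103 a lower response in the T-DNA line, and 87 differed at least 2-fold.

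In the heat shock list 2 responses were called lower in the T-DNA line, those of HSFB2A (by -1.23 ± 0.21) and HSP23.6. For HSP23.6 no weaker response can be read from the values, since only 1 of 6 control arrays measured it above background. HSP17.6C, HSP22.0 and HSP17.4 were above background on no control array of Col-0. These genes and HSP23.6 stay in the list values that follow. There were 11 lower and 1 higher adjusted over the list alone (median -0.36, camera adjusted p = 2.8e-07; adjusted p = 0.374 with an estimated correlation). COR47 (-1.02) and MYB96 (-0.91) were called in the abscisic acid list, or 8 lower and 1 higher adjusted over the list alone (median -0.31, camera adjusted p = 1.41e-05; adjusted p = 0.374 with an estimated correlation). Camera also called the endoplasmic reticulum list (median 0.27, 0 called and 1 higher adjusted over the list alone, adjusted p = 0.00164; adjusted p = 0.374 with an estimated correlation), NLR receptors (median 0.10, 0 called and 0 adjusted over the list alone, adjusted p = 0.0153; adjusted p = 0.374 with an estimated correlation) and antioxidants (median -0.25, 0 called and 0 adjusted over the list alone, adjusted p = 0.0153; adjusted p = 0.19 with an estimated correlation). It called phenylpropanoids (median 0.37, 0 called and 1 higher adjusted over the list alone, adjusted p = 0.00302; adjusted p = 0.374 with an estimated correlation), guard cell genes (median 0.37, 0 called and 3 higher adjusted over the list alone, adjusted p = 0.0078; adjusted p = 0.19 with an estimated correlation) and dividing cell genes (median 0.55, 0 called and 3 higher adjusted over the list alone, adjusted p = 6.25e-04; adjusted p = 0.19 with an estimated correlation). The other 12 lists were not called by camera, at adjusted p of 0.0551 or above. Among their members XTH22 and XTH30 (-1.30 ± 0.20) had a lower and WAK1 (0.87) a higher response, in each case also adjusted over the list alone, where 1 clock gene was lower and the sugar list had 1 higher and 1 lower. The potyvirus list had a median of 0.05 and a mean of 0.02 where camera leaned down. The salicylic acid list had a median of 0.06 and a mean of -0.04 where it leaned up. The count of 149 was 64 without Col-0 control replicate 1, 92 without Col-0 control replicate 3, 72 without Col-0 stress replicate 1, 64 without T-DNA control replicate 4 and 99 without T-DNA stress replicate 4. With slide as a random block it was 232, and with variances not tied to the mean 91.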

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

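The test that leaves out each stress array, the list of touch and wound genes, the count of genes per chromosome and the count without pairs of one gene family were chosen only after the result was seen. Among 192 results checked in the 4 stress arrays of the T-DNA line, 11 had 1 array far from the other 3, where chance would mark about 1 in 20 groups, or 9.6. The number given is the gap to the nearest array divided by the whole range. It was 0.896 for HSP23.5 (replicate 1 at 0.91, the others at a median of 1.93), 0.956 for AT5G11330 (replicate 1, 1.72 and 1.64), 0.982 for ERD10 (replicate 2, 3.78 and 4.22), 0.869 for ZAR1 (replicate 2, 3.11 and 3.28) and 0.877 for BZIP34 (replicate 2, -3.73 and -4.05). It was 0.864 for RTM1 (replicate 3, -4.22 and -3.28), 0.953 for RTM2 (replicate 3, -2.91 and -2.20) and 0.935 for the mean of the expansin list (replicate 3, -1.643 and -1.15). Replicate 4 was the far one for AT1G27020 (0.869; -4.83 and -4.57), PR5 (0.92; -2.28 and -1.61) and RTM3 (0.874; -4.63 and -5.10).

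The test of the difference between the stress responses of both lines, the same as in the last comparison above, marked 29 named genes and 8 lists. Most of these genes were named because that test called them. Their number thus follows from the naming rule and adds no support. The response of the T-DNA line was lower for PHI-1 (-3.51), XTH22 (-3.38), DIC2 (-3.12), DREB26 (-3.02), CAF1a (-2.88), ACS6 (-2.41), AT1G07135 (-2.29), CML23 (-2.27), MYB77 (-2.25), AT1G50040 (-2.21), TCH2 (-2.15), AT3G19680 (-2.14), XTH30 (-1.30), HSFB2A (-1.23), COR47 (-1.02), MYB96 (-0.91) and AT4G23493 (-0.88). HSP23.6 was also marked (computed value -1.45), but only 1 of 6 control arrays measured it above background, so no weaker response can be read from it. The response was higher for EXPA16 (1.82), AT5G55450 (1.79), TED7 (1.77), AT4G14390 (1.74), AT5G45850 (1.63), RLP38 (1.53), AT5G59670 (1.36), XTH25 (1.36), AT3G27640 (1.34), CYCA3;1 (1.27) and WAK1 (0.87). The lists had median differences of -0.364 (heat shock), 0.265 (endoplasmic reticulum), -0.309 (abscisic acid), 0.103 (NLR receptors), -0.25 (antioxidants), 0.373 (phenylpropanoids), 0.365 (guard cells) and 0.545 (dividing cells), and none of them passed with an estimated correlation.

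Of 38 heat shock genes, 6 were called lower in the stressed T-DNA line than in stressed Col-0 and 32 were not called (list median -0.621; camera adjusted p = 1.53e-19, and 0.212 with an estimated correlation). The median was at most -0.465 with any 1 of the 7 stress arrays left out (that of T-DNA replicate 1), which argues against a single array as the whole cause. It was -0.225 within slide 1, with 1 array per line, and -0.974 within slide 3, which argues against slide or scan day as the whole cause. A weaker response of all genes stays open: random lists matched on stress response had a median of -0.211, with 95% of them between -0.386 and -0.055. The list median of -0.621 lay below that range, but the random lists lack the correlation among heat shock genes, so they cannot decide. No random lists were drawn within a slide, so the medians of slides 1 and 3 cannot be set against that range. An effect of the insertion was not tested, and a second insertion allele or complementation would be needed to decide it.

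Touch and wound genes, 22 of them listed after the result was seen, had a median difference of 0.456 between control plants of the T-DNA line and control Col-0, with 4 called higher (camera p = 1.94e-09, and 0.084 with an estimated correlation). In stressed plants the median was -0.527 (p = 0.0992 with an estimated correlation), with 2 of 22 above 0, and the difference of responses had a median of -1.264 (p = 0.0212), but for the 13 members not seen before these were -0.39 (p = 0.203) and -0.937 (p = 0.0709). In control plants these 13 had a median of 0.203 (limma camera p = 0.227 with an estimated correlation), and within slides the median of all 22 was as low as 0.051 (slide 4) against 0.604 (slide 2), which leaves handling and slide open. Leaving out 1 control array lowered that of all 22 to 0.184 (T-DNA replicate 4) or 0.185 (Col-0 replicate 2), so the difference may rest largely on those arrays. The touch and wound list shares members with other lists, among them XTH22 (expansins), JAZ1 (jasmonate), and ZAT10 and ZAT12 (antioxidants). ZAT10 (-1.62) was the lowest antioxidant member in the difference of responses, so those lists are not independent of it. Whether the insertion plays a part in the difference of touch and wound genes was not tested.

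Of 43 genes called between the lines in both treatments, 36 had the same direction, 22 higher and 14 lower, and 7 the opposite. If the comparisons were independent, 1.63 higher and 1.06 lower would be expected. They are not fully so, since both use the same variance estimate of each gene. Across all tested genes the line differences in control and stressed plants correlated at only 0.104. Within slides that hold both lines 100% of the 36 genes kept their direction. The genes were called from these same arrays, so this check cannot decide on slide or scan day. The 36 genes lay on all 5 chromosomes, at most 25% of them on 1, so they do not all lie in 1 linked segment. Their positions cannot tell whether 1 locus acts on genes elsewhere. On chromosome 5 lay 19.4% of the 36 genes, against 23.1% of tested genes. The 36 genes held 4 neighbouring pairs, on chromosomes 1, 2 and 5, more than random gene sets (median 0, permutation p = 0.0037). Without pairs of the same gene family they held 2 (permutation p = 0.13). The random sets kept their family pairs, so this p-value leans high. Linked segments as the cause of a part of the genes stay open. Pairs over 10 tested genes apart were not counted, and neither the insertion nor another heritable difference between the lines was tested.

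Regrouping the same arrays never called as many genes as the real grouping. For the T-DNA line under stress 1 of 35 splits, the real one, reached 12404 and the next highest 6792. Between the stressed lines 1 of 35 reached 288 and the next 12. For the difference of responses, 1 of 100 drawn splits, the real one, reached 149 and the next 96. Only 10 splits exist for stress in Col-0 (12412, the next 0; 1 reached it) and for the lines in control plants (366, the next 1), too few to judge.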

How the results depend on the processing

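Scan day as a block and the fit without both arrays of extreme detection were chosen only after the results were seen. Of 378 results for named genes and called lists, 316 kept direction and call with normexp, 343 with quantile normalization, 373 with median centring, 377 with the deposited values and 322 with slide as a fixed block. In that last setting every difference between stress and control rests on the 1 stress array of slide 4, T-DNA line replicate 4. Where a result changed, the cause was not tested unless the construction of the alternative gives it. Direction turned after quantile normalization for RPL10A (0.0019), RPS6A (0.0047) and RPL27AC (0.1577) in Col-0 and for RD22 (0.002), LOX2 (0.4291), RPL27AC (0.0642) and RPS6A (0.0805) in the T-DNA line. It turned with the mean of probes for TT19 (0.9548 in Col-0, 2.0206 in the T-DNA line) and HSP70-3 (0.1219), which average different probes, and with slide as a fixed block for BIP3 (0.3231). With normexp, the median of all genes under stress in the T-DNA line moved to 0.111. The near-even split of called genes turned after quantile normalization for stress in Col-0 (6470 higher, 5873 lower). For stress in the T-DNA line it turned, among other settings, with median centring (5967 and 6381) and with the stricter filter (5600 and 5800).

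The correlation of the responses was 0.895 with normexp and 0.81 without the filter, which lets dim genes in. Camera called 8 lists between the stressed lines with normexp (4 before), 11 under stress in the T-DNA line without the filter (7 before), and 0 in all 5 comparisons with an estimated correlation. Genes differing between the stressed lines numbered 185 without the filter, 457 with slide as a random block, 174 with only the groups compared, 178 without a variance trend and 124 without both arrays of extreme detection, against 288. The stress response in Col-0 had 7924 genes with slide as a fixed block, where the difference of AT5G45000 was 1.4242. The difference of responses had 232 genes with slide as a random block and 91 without a trend. At 2-fold or more, by construction fewer, 4134, 3859, 97, 48 and 87 genes remained. Leaving out saturated genes removed none, and the difference of responses has no fit on fewer groups.

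The replicate number as a block called 156 genes between the stressed lines, and 12392, 12173, 255 and 151 in the others. Pairs of arrays with the same number correlated from -0.289 to 0.214, with a median of 0.055 and 5 of 16 above 0.1, those with other numbers had a median of -0.015 with 9 of 47 above 0.1, and those on the same slide 0.098 with 6 of 12. Only 2 of 13 arrays correlated best with their own number, and the numbers were not taken as pairs.

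With 1 array left out, the counts ranged from 11353 to 12664 (stress in Col-0), 11314 to 12502 (stress in the T-DNA line), 156 to 386 (lines, control), 126 to 411 (lines, stress) and 64 to 202 (difference). AT5G45000 ranged from -3.77 to -3.54, -2.61 to -2.18, -2.27 to -1.97, -1.0479 to -0.6212 and 1.05 to 1.48, the correlation from 0.916 to 0.926, and the lists called from 5 to 7, 7 to 8, 4 to 11, 3 to 6 and 7 to 11.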
